A study of Mus musculus with 6 samples.

How the data were processed

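Bronchial epithelial cells brushed from the main bronchi of C57/B6 mice aged 6 weeks were profiled on Affymetrix GeneChip Mouse Gene 1.0 ST arrays, with 1 array per sample. Per the labels' protocols, the airways were lavaged before brushing, and brushing followed the challenge by 24 h. The challenge was an extract of the mould Alternaria (3 samples) or phosphate-buffered saline, PBS (3 samples). The labels do not say that samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

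The authors deposited 1 value per probe set and array, and these values are linear intensities, not logarithms, as judged from their range. Per the submitters' processing notes, MAS5 was used. Its version and role, the background correction, the summarization and the scaling are not given in the sources used here. The 6 columns have medians between 89.6 and 98.9 and different upper tails, so a common level had been set without making the distributions identical. No detection call was used here, so no bound could be set on dim probe sets. As a low-signal reference, the 1210 probe sets of olfactory and vomeronasal receptor genes had a median intensity of 22.8 and a 95th percentile of 73.9, against a median of 96.2 for the whole table. The number of arrays limits the precision.

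Probe sets were named from the platform annotation. Of 35557 probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had none here. Symbols were checked through Entrez IDs against the RefSeq gene table, which changed 0 symbols and did not hold the IDs of 91 probe sets. Coordinates were not used here, since no genome build was named.

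The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Values were used as deposited, as log2(value + 1). Fold changes are on that scale, which understates the change of dim genes. The 21789 single-gene probe sets, for 19938 genes, were tested with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, no variance trend, not robust, no replicate block). P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05.

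Gene lists, 16 of pathways and 17 of cell types, held 676 members, of which 625 were measured. They were tested with limma's camera (two-sided, preset inter-gene correlation of 0.01), with 1 probe set per gene, the one with the highest mean, and all genes tested as background. P-values were adjusted over the 33 lists. The lists covered type 2 cytokine response, mucus and goblet cell, alarmins, eosinophil and type 2 chemokines, NF-kappaB targets, antimicrobial and acute phase, interferon response, MHC class II, cell cycle, unfolded protein response, NRF2 targets, airway remodelling, epithelial junctions, eicosanoid synthesis, xenobiotic metabolism and immediate early genes. The cell types were ciliated, club, basal, tuft and neuroendocrine, alveolar, eosinophil, neutrophil, alveolar macrophage, monocyte and dendritic, T and ILC2, B and plasma, NK, mast and basophil, fibroblast and smooth muscle, endothelial, cartilage and red blood cell.

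The text names genes by a fixed rule. The rule took Retnla, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, and up to 4 members per list with the smallest limma p. The genes with the largest rise or fall had to separate the 2 groups without overlap and have a group mean above the median of all probe sets. Places left free were filled by the smallest unadjusted p, and such genes are described as not past the threshold. Il33, Tslp, Il25, Muc5ac, Clca1, Ccl11, Ccl24, Scgb1a1 and Foxj1 were named whatever their values. Not all genes that the rule allows are named. Olfr342 and the genes of skeletal muscle, parathyroid, thyroid and exocrine gland were chosen after their values were seen, apart from Chga, which the rule took.

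The tests were first run on simulated data with the spread of these arrays. For Alternaria against PBS over 21789 probe sets, 79.7% of simulated changes of 1 on the log2 scale were found, 97.5% of changes of 2 and 100% of changes of 4, with 5.59% false among the calls. For the list test over 19938 genes, 20 of 20 lists shifted by 0.5 were found and 0 of 20 unshifted lists were called. The simulated genes were independent of each other, unlike real ones. Simulated changes were placed only in probe sets above the median level, with 200 changed per simulation. The shares found therefore do not hold for dim probe sets or for data with fewer changes.

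Alternatives were quantile normalization, median centring, scaling to the 75th percentile, a pseudocount of 16, filters on dim probe sets, other sets of probe sets, a variance trend with robust eBayes, array weights, the replicate number as a block, other thresholds and each array left out in turn. For the lists, they also included an estimated correlation, limma's fry and leaving out shared members. An alternative without Alternaria replicate 2 and PBS replicate 1 was added after seeing transcripts of other tissues on them. It left 2 arrays per group. The arrays kept carried such transcripts too, of muscle on PBS replicate 3, of gland on Alternaria replicate 3 and thyroglobulin on each. It is thus not a comparison free of other tissues. Another 5 gene lists were also added after the data were seen. Plots were drawn with matplotlib version 3.10.9 in Python version 3.11.15.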

Results

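Gene expression was measured in epithelial cells brushed from the large airways of mice 24 h after challenge with Alternaria, a mould whose extract is used as an airway allergen, or with PBS as the control. Each group had 3 arrays of 35557 probe sets. Median intensities lay between 95.3 and 96.1 on the Alternaria arrays and between 89.6 and 98.9 on the PBS arrays. Across genes, which are not independent replicates, Pearson's r of the log2 values was 0.968 to 0.988 within groups and 0.962 to 0.982 between groups. The first principal component held 35.3% of the variance and set Alternaria replicate 2 (score 50.9) apart from the other 5 arrays (scores -20.0 to -2.78). On the second, with 23.6%, PBS replicate 1 stood apart at -36.7.

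Transcripts known from other tissues differed between arrays. Acta1, the actin of skeletal muscle, had an intensity of 10278 on Alternaria replicate 2 and between 178 and 831 on the others. Muscle genes were higher on PBS replicate 3 too, by a median of 2.29 on the log2 scale over the other 5 arrays (28 genes). Pth, which encodes parathyroid hormone, read 3165 on Alternaria replicate 2 and at most 21.5 elsewhere. Tg, the thyroid hormone precursor thyroglobulin, ran the other way, at 37.3 on Alternaria replicate 2 and from 5146 to 10250 on the other 5 arrays. A transcript known from the thyroid was thus bright on all arrays but that one, in both groups, and its source was not tested. Car6, a carbonic anhydrase secreted by salivary glands, reached 56860 on PBS replicate 1. It read 6608 and 1709 on Alternaria replicates 2 and 3 and 59.1 to 67.3 on the remaining arrays. These genes were chosen after their values were seen.

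**Figure D1:**
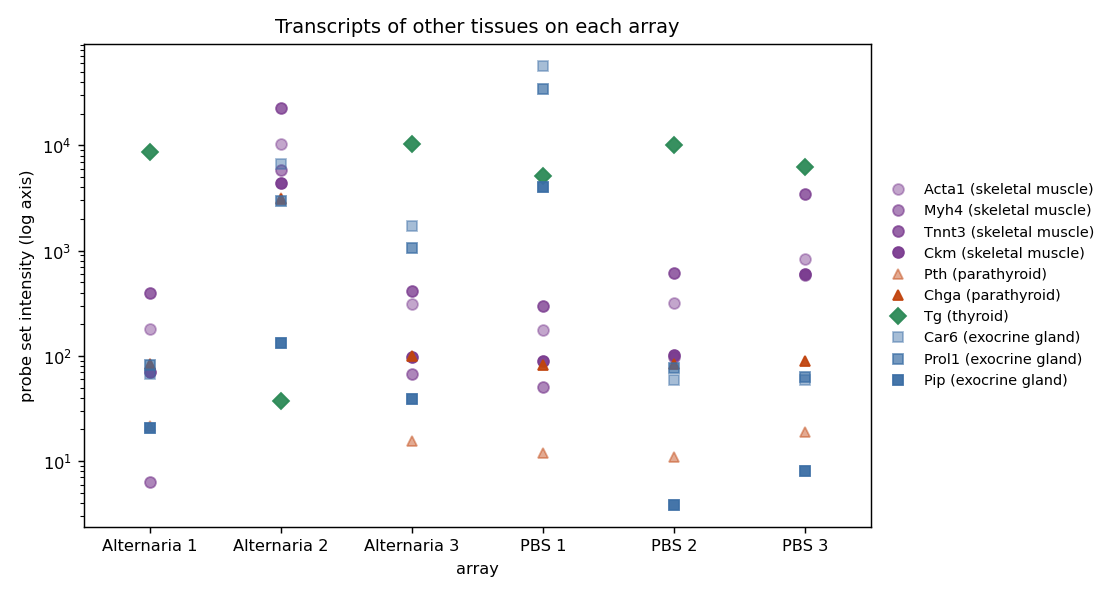
Intensity (log axis) of 10 transcripts of skeletal muscle, parathyroid, thyroid and exocrine gland on each of the 6 arrays, 1 point per gene and array. Muscle genes and Pth stand highest on Alternaria replicate 2, where Tg is at 37.3, and Car6 reaches 56860 on PBS replicate 1.

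The comparison of Alternaria with PBS asked which epithelial transcripts differed 24 h after allergen exposure. Retnla, a secreted resistin-like protein induced by type 2 cytokines, rose 20.4-fold (95% interval 17.4 to 23.9), from an intensity of 402 ± 9.08 to 8245 ± 687 (SD, n = 3 per group). Chil4, a chitinase-like protein of the airway epithelium, rose 109-fold (80.8 to 146), from 31.7 ± 4.54 to 3583 ± 769. Retnlg, a neighbouring paralog of Retnla, rose 11.7-fold (8.57 to 15.9), from 24.5 ± 5.47 to 295 ± 52.5. Pla2g4c, a cytosolic phospholipase A2, rose by 4.82 (3.91 to 5.73) on the log2 scale, from 10.5 ± 1.62 to 356 ± 165. PBS intensities of Chil4, Retnlg, Pla2g4c and Slc26a4 were within the range of olfactory receptor probe sets, whose 95th percentile was 73.9, so these folds depend on the low-signal level. For Slc26a4 the Alternaria values, 58.2 to 69.4, were in that range too, as were both group means of Ccl24, E2f8, Krt79, Clec4d and Rnase2a.

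In all, 8 of 21789 probe sets rose and 0 fell in limma at an adjusted p under 0.05. The others that rose were Fer1l6, a ferlin family member, from 232 ± 23.9 to 949 ± 14.9, and Slc26a4, the anion exchanger pendrin, from 17.6 ± 1.59 to 64.4 ± 5.71. Foxa3, a transcription factor of goblet cells, rose 2.48-fold from 111 ± 11.6, and Kcnk6, a potassium channel, rose 2.34-fold from 101 ± 3.18. Limma's adjusted p was 1.9e-05 for Retnla (probe set 10436095), 3.4e-05 for Chil4 (10501026) and 0.0018 for both Retnlg (10436100) and Fer1l6 (10424287). It was 0.0044 for Slc26a4 (10399854), 0.016 for both Pla2g4c (10550131) and Kcnk6 (10561702), and 0.032 for Foxa3 (10560431). All 3 Alternaria values exceeded all 3 PBS values for each of these 8 genes.

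Calls on Foxa3 and Kcnk6 were lost whichever array was left out (adjusted p from 0.088 to 0.218 and from 0.067 to 0.123). That on Pla2g4c was lost without any array but Alternaria replicate 1 (0.059 to 0.124). Without both Alternaria replicate 2 and PBS replicate 1, a setting chosen after seeing the data, 6 probe sets passed. These were Retnla, Chil4, Retnlg and Fer1l6 with Lcn2 (adjusted p = 0.014) and Chil3 (0.045), and the adjusted p of Slc26a4 was 0.102. That setting left 2 arrays per group, and the arrays kept still carried transcripts of other tissues.

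**Figure D2:**
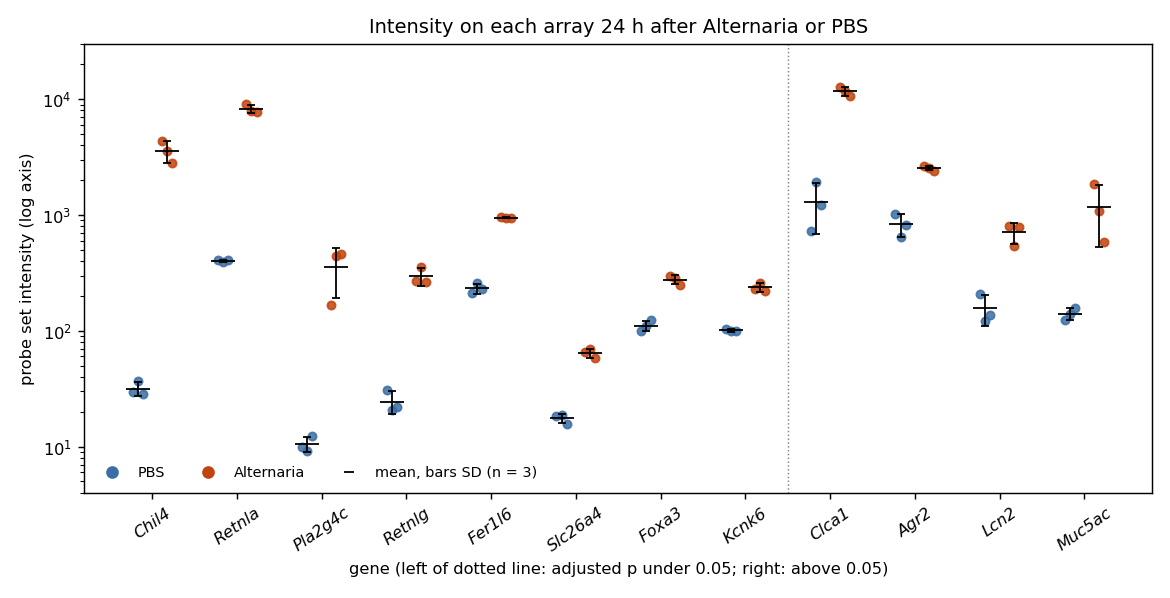
Intensity (log axis) of 12 genes on each PBS (blue) and Alternaria (orange) array, 1 point per array, with group means and SD bars (n = 3 per group). The 8 genes left of the dotted line passed the threshold, with Retnla at 402 ± 9.08 on PBS and 8245 ± 687 on Alternaria arrays, and the 4 to its right did not.

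Several genes with large differences missed the threshold. Clca1, a secreted regulator of mucus, averaged 11765 ± 1062 after Alternaria and 1293 ± 603 after PBS (limma adjusted p = 0.0503). Its adjusted p was 0.041 without PBS replicate 1, 0.023 without PBS replicate 2 and 0.182 to 0.287 without each of the others. Agr2, a disulfide isomerase needed for mucin folding, differed 3.11-fold (adjusted p = 0.063, and 0.043 without PBS replicate 1 but 0.095 to 0.316 without each of the others). Lcn2, an iron-siderophore-binding protein, differed 4.59-fold (adjusted p = 0.075). Pdia5, another disulfide isomerase, averaged 436 ± 25.7 against 196 ± 32.1, and Cldn22, a claudin, 546 ± 69.1 against 271 ± 12.2 (both adjusted p = 0.096).

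Among lower values, none passed in limma, although 629 probe sets were lower and 836 higher at an unadjusted p under 0.05, where 1089 in all would be expected by chance. Other settings called between 0 and 4 lower probe sets. The smallest p among lower values was that of Olfr342, an olfactory receptor gene (adjusted p = 0.053), at 9.50 ± 1.15 against 20.7 ± 0.409, both in the low-signal range. It was chosen after its values were seen. Among genes bright enough for the naming rule, the smallest p belonged to Adh1, an alcohol dehydrogenase, with a log2 fold change of -0.78 ± 0.096 (SE) and an adjusted p of 0.131. Pxdc1 followed at -0.63 and Atp7b, a copper transporter, at -0.77. The keratin Krt13 stood at -0.99, the transcription factor Klf15 at -0.54, the cell cycle inhibitor Cdkn1c at -0.59 and the membrane protein Emp1 at -0.67. Groups did not overlap for 12.96% of probe sets, against 10% by chance.

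Of the 33 gene lists, 9 were higher and 4 lower after Alternaria in camera with its preset correlation. With an estimated correlation, only the type 2 cytokine response held. With limma's fry, the type 2, mucus, unfolded protein response, eosinophil chemokine, antimicrobial and neutrophil lists held. In the neutrophil list, only Retnlg and Lcn2 rose adjusted over the list alone. The same camera test gave 5 to 12 lists when the 6 arrays were divided in the 9 other ways.

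**Figure D3:**
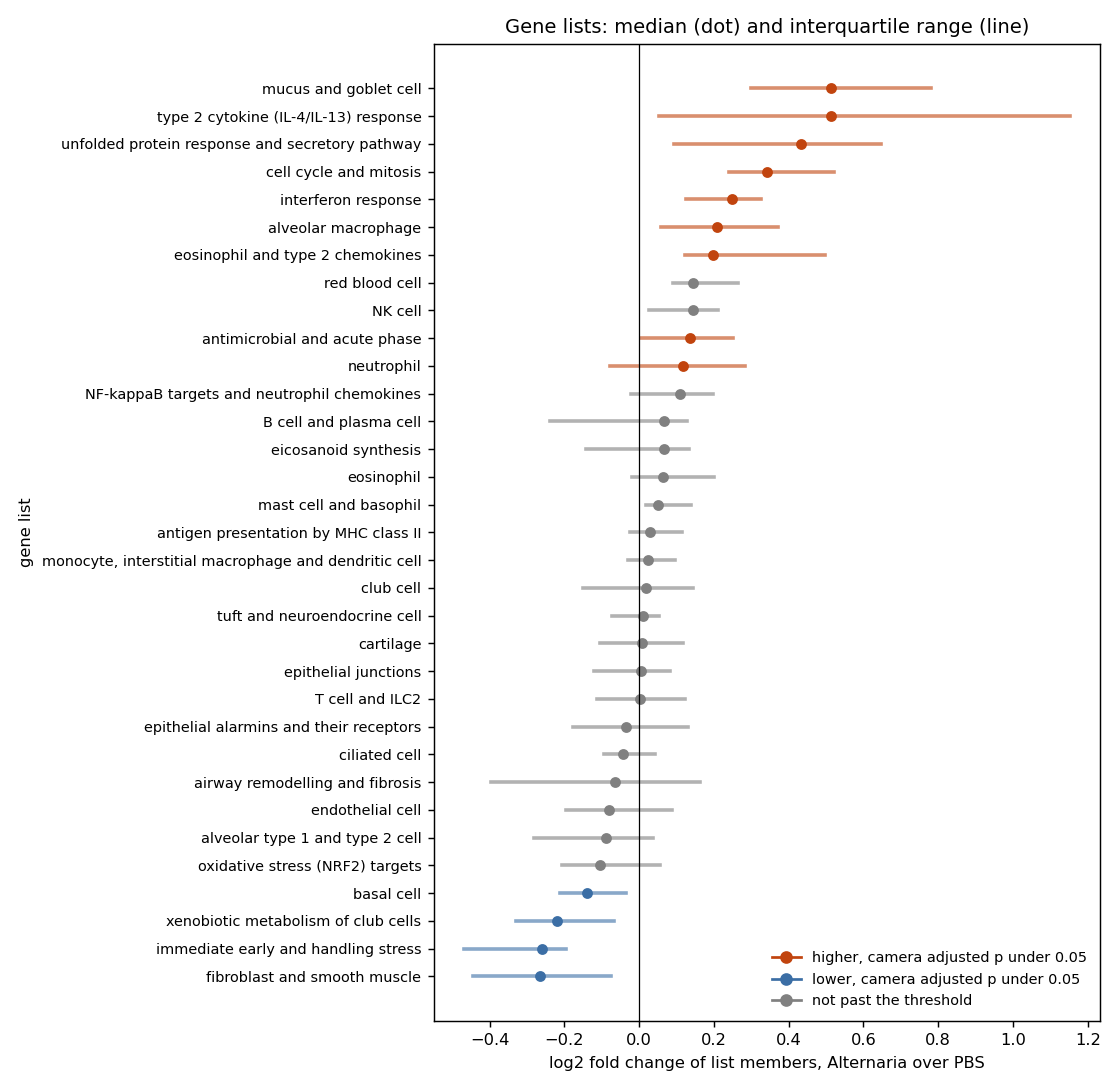
Median log2 fold change (dots) and interquartile range of the members (lines) of 33 gene lists, Alternaria over PBS. Orange and blue mark the 9 higher and 4 lower lists at a camera adjusted p under 0.05 with the preset correlation. The mucus and type 2 lists have medians of 0.51 here.

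The type 2 cytokine response list, of genes induced by IL-4 and IL-13, was higher as a group (camera adjusted p = 3.7e-12, and adjusted p = 0.039 with an estimated correlation). Of its 29 measured members, 3 rose over all genes, Retnla, Chil4 and Slc26a4. Adjusted over the list alone, 8 rose. Its median log2 fold change was 0.51, but 0.29 without Alternaria replicate 2, 0.36 without both doubted arrays and 0.15 without members shared with other lists (adjusted p = 2.7e-05). The mucus and goblet cell list was also higher (adjusted p = 5.1e-23), with 23 of 25 members above 0. Its adjusted p = 0.076 with an estimated correlation. Only Foxa3 passed over all genes, while 20 members rose adjusted over the list alone. Muc5ac, the main inducible airway mucin, averaged 1173 ± 644 against 141 ± 17.6 (limma adjusted p = 0.164 over all genes, and 0.039 without Alternaria replicate 3 but 0.218 to 0.535 without each of the others). Muc5b, the mucin of resting airways, averaged 7394 ± 1076 against 5320 ± 376.

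Genes of the unfolded protein response and secretory pathway were higher as a group, with 20 of 24 members above 0 and a median log2 fold change of 0.43 (camera adjusted p = 8.8e-14). The group had adjusted p = 0.095 with an estimated correlation. None of them passed over all genes, and 15 rose adjusted over the list alone. Hspa5, the chaperone BiP of the endoplasmic reticulum, averaged 3747 ± 240 against 2082 ± 320, and its cofactor-associated protein Sdf2l1 555 ± 59.8 against 309 ± 24.7. The disulfide isomerases Pdia6 and Pdia4 differed 1.67-fold and 1.57-fold. A second probe set of Pdia4, at an intensity near 103 in both groups, showed a log2 fold change of 0.0032.

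Eosinophil and type 2 chemokines were higher as a group (camera adjusted p = 0.0015), with 13 of 14 members above 0 and none past either adjustment. They had adjusted p = 0.131 with an estimated correlation, and their median of 0.20 became 0.59 with only probe sets above the median. Ccl24, an eosinophil chemoattractant, averaged 68.3 ± 6.67 against 46.8 ± 7.93, Ccl6 277 ± 57.3 against 158 ± 49.9 and Ccl9 218 ± 18.7 against 148 ± 39.4. Ccl11, also an eosinophil chemoattractant, read 192 on Alternaria replicate 2 and 45.8 and 51.6 on the other Alternaria arrays, against 34.5 to 47.7 on PBS arrays. The alarmin list did not pass (adjusted p = 0.890), with a median of -0.036, a mean of 0.014 and a test direction of lower. The alarmin cytokines Il33, Tslp and Il25 had log2 fold changes of 0.093 ± 0.206, 0.38 ± 0.247 and 0.11 ± 0.138 (SE). Tslp, at 7.23 ± 2.52 on PBS arrays, and Il25, at 55.0 ± 6.40, were in the low-signal range in both groups. The sign of Il33 turned without Alternaria replicate 2, to -0.14.

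Antimicrobial and acute phase genes were higher as a group (camera adjusted p = 1.4e-04, and adjusted p = 0.095 with an estimated correlation). Of 26 members, 3 rose adjusted over the list alone and none over all genes. These were Lcn2, Pigr, the transporter of IgA across epithelia, at 4142 ± 380 against 2567 ± 150, and Cp, the copper protein ceruloplasmin, at 3524 ± 295 against 2221 ± 283. NF-kappaB targets and neutrophil chemokines did not pass (adjusted p = 0.159), but did without Alternaria replicate 2 (0.0072), against 0.149 to 0.482 without each of the others. They also passed without both doubted arrays (0.016) and without members shared with other lists (0.036). Cxcl5, a neutrophil chemokine, averaged 99.2 ± 33.0 against 38.4 ± 10.3 (limma adjusted p = 0.433).

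Interferon response genes were higher as a group (camera adjusted p = 2.3e-04), with 25 of 27 members above 0 and none past either adjustment. The list had adjusted p = 0.778 with an estimated correlation, 0.103 without PBS replicate 2 and 0.397 without both doubted arrays. Its median of 0.25 ranged from 0.11 to 0.48 with 1 array left out. Zbp1 differed 1.56-fold, Oas2 1.32-fold and Mx1 1.78-fold. Cell cycle and mitosis genes were higher as a group, with 37 of 38 members above 0 (camera adjusted p = 1.5e-09). They had adjusted p = 0.596 with an estimated correlation and no member past either adjustment. Their median of 0.34 ranged from 0.21 to 0.55 with 1 array left out. The replication licensing factors Mcm2 and Mcm3 differed 1.37-fold and 1.72-fold, and E2f8, a transcription factor of the cell cycle, 1.45-fold.

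Of the 4 lower lists, xenobiotic metabolism of club cells had 3 of 22 members above 0 (camera adjusted p = 9.2e-06). It had adjusted p = 0.307 with an estimated correlation. Adh1 and the flavin monooxygenases Fmo1 and Fmo2, with log2 fold changes of -0.52 and -0.56, fell adjusted over the list alone and did not pass over all genes. Ces1f, a carboxylesterase, stood at 0.74. Immediate early and handling stress genes were lower as a group (camera adjusted p = 2.8e-05, and adjusted p = 0.550 with an estimated correlation). Their median of -0.26 ranged from -0.41 to -0.18 with 1 array left out. Fosb, at -1.29, fell adjusted over the list alone. Its fellow members Atf3 and Hspa1a stood at -1.19 and -1.25, and Klf4 at 0.41. Hspa1a, a heat shock protein, ranged from 443 to 1781 on PBS arrays and from 355 to 377 on Alternaria arrays.

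Basal cell genes were lower as a group (camera adjusted p = 0.021, and adjusted p = 0.778 with an estimated correlation). The call was lost without Alternaria replicate 1 (0.158), Alternaria replicate 2 (0.091), PBS replicate 1 (0.223) or PBS replicate 3 (0.169) and with only probe sets above the median (0.066), and was 0.431 without both doubted arrays. Trp63, the transcription factor of basal cells, had a log2 fold change of -0.32 and Pdpn, a membrane mucoprotein, 0.52. Fibroblast and smooth muscle genes were lower as a group (adjusted p = 0.018, and adjusted p = 0.873 with an estimated correlation). They gave 0.587 without Alternaria replicate 3, 0.810 without PBS replicate 3 and 0.053 with only probe sets above the median, and the median of -0.26 ranged from -0.64 to -0.027 with 1 array left out. Without both doubted arrays the adjusted p was 2.6e-12 and the median -0.71. The smooth muscle genes Acta2 and Cnn1 stood at -0.76 ± 0.433 and -0.83 ± 0.466 (SE), and at -1.53 and -1.56 without both doubted arrays. Cnn1 read 37.7 on PBS replicate 1, which is left out there, and 123 and 134 on PBS replicates 2 and 3. Alternaria arrays read 40.2 to 58.9. Acta2 read 334, 792 and 894 on PBS replicates 1 to 3 and 265 to 573 on Alternaria arrays. The larger fall of these genes thus depends on which PBS arrays are kept. Neither list had a member past either adjustment.

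Among epithelial cell types, ciliated cell genes did not pass (camera adjusted p = 0.466, median -0.042). The list was lower without Alternaria replicate 1 (0.0011) and without PBS replicate 2 (0.039), against 0.411 to 0.967 without each of the others. Foxj1, the regulator of motile cilia, averaged 1124 ± 168 against 1243 ± 175, and Tekt2, a ciliary tektin, had a log2 fold change of -0.34. Club cell genes did not pass (0.648). Scgb1a1, the main club cell secretory protein, averaged 11478 ± 631 against 11512 ± 386, with a 95% interval of the log2 fold change from -0.22 to 0.21. Adjusted over the list alone, Pigr and Muc5b rose and Selenbp1, a selenium-binding protein, fell. Alveolar genes did not pass (0.316). Of the surfactant proteins in that list, Sftpa1 rose and Sftpb fell adjusted over the list alone, at 0.85 and -1.12, and the lung chemokine Cxcl15 rose at 1.54. None of the 3 passed over all genes. Tuft and neuroendocrine genes did not pass either (0.836).

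Of the immune cell lists, neutrophil genes were higher as a group (camera adjusted p = 0.037, and adjusted p = 0.298 with an estimated correlation). The call was lost without Alternaria replicate 1 (0.171), PBS replicate 1 (0.080) or PBS replicate 3 (0.169), with quantile normalization (0.108) or without members shared with other lists (0.101). Their median of 0.12 was 0.073 without both doubted arrays and 0.068 with only probe sets above the median. Of its 23 members, only Retnlg rose over all genes, and Retnlg and Lcn2 adjusted over the list alone. Clec4d, a myeloid lectin, averaged 25.4 ± 4.19 against 18.5 ± 1.40. Alveolar macrophage genes were higher as a group (adjusted p = 0.018, and adjusted p = 0.778 with an estimated correlation). They gave 0.125 without Alternaria replicate 1, 0.105 without Alternaria replicate 3, 0.445 without PBS replicate 1 and 0.062 without members shared with other lists, and the median of 0.21 ranged from 0.067 to 0.27 with 1 array left out. Chil3, a chitinase-like protein of macrophages, averaged 860 ± 546 against 155 ± 120 with overlapping groups (limma adjusted p = 0.703). Its log2 fold change of 2.76 ranged from 1.62 to 3.54 with 1 array left out. Krt79 differed 1.48-fold. Eosinophil genes did not pass (0.226), and Rnase2a, an eosinophil ribonuclease, read 18.6 ± 1.99 against 12.6 ± 2.93.

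The remaining cell type lists did not pass. Camera's adjusted p was 0.664 for monocytes, interstitial macrophages and dendritic cells, 0.650 for T cells and ILC2, 0.984 for B and plasma cells, 0.316 for NK cells and 0.647 for mast cells and basophils. It was 0.647 for endothelial cells, 0.650 for cartilage and 0.448 for red blood cells. Without PBS replicate 2, NK cell (0.039) and red blood cell (0.0015) genes were higher, and without PBS replicate 1 endothelial genes were lower (0.013). Leaving out each of the other arrays gave 0.171 to 0.810, 0.288 to 0.969 and 0.288 to 0.997 for these lists. Only 4 of the 13 members of the red blood cell list were measured. Il5, a T cell and ILC2 cytokine, fell adjusted over the list alone but read only 16.2 ± 1.56 against 24.0 ± 0.533, in the low-signal range. The test and the median differed in sign for tuft and neuroendocrine cells, T cells and epithelial junctions. The test and the mean differed for alarmins, tuft and neuroendocrine cells, T cells, B cells and cartilage.

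The other pathway lists did not pass. Antigen presentation by MHC class II (camera adjusted p = 0.650) held Ctss, a lysosomal protease, at 606 ± 130 against 473 ± 130. NRF2 targets (0.136) held the antioxidant enzymes Cat and Gsr at log2 fold changes of -0.39 and 0.38, and were lower without PBS replicate 2 (0.0041), against 0.145 to 0.825 without each of the others. In airway remodelling and fibrosis (0.485), Lox, a collagen cross-linking enzyme, rose and Timp3, a metalloproteinase inhibitor, fell adjusted over the list alone, at 0.70 and -0.98. That list was lower without PBS replicate 1 (0.040), against 0.425 to 0.792 without each of the others, and without both doubted arrays (0.0091). Fn1, fibronectin, averaged 640 ± 347 against 265 ± 106, with 1040 on Alternaria replicate 2. Its log2 fold change of 1.22 was 0.80 without that array and 0.52 without both doubted arrays. Epithelial junctions (0.648) held Jup at -0.33 and Cldn10 at 0.47. In eicosanoid synthesis (0.493), Pla2g4c and the lipoxygenase Alox12e, at 1.07, rose adjusted over the list alone.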

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

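One setting, without Alternaria replicate 2 and PBS replicate 1 ("both left out"), was chosen after the data were seen. Against 8 higher probe sets, a pseudocount of 16 gave 17, only probe sets above the median 21, all probe sets, with or without a symbol, gave 5, a variance trend with robust eBayes 31, and an adjusted p under 0.10 gave 13. Leaving out 1 array gave 6 to 7, and both left out 6. Against 0 lower, quantile normalization, scaling to the 75th percentile, a pseudocount of 16, 1 probe set per gene and an adjusted p under 0.10 each gave 1. The filter at the median and all probe sets each gave 2, and the variance trend 4. Leaving out 1 array gave 0. Against 9 higher and 4 lower lists, an estimated correlation gave 1 and 0. With fry, 0 lists were lower, and above the median 2 were. Leaving out 1 array gave 7 to 10 higher and 2 to 6 lower lists. Filters test fewer probe sets, and the cause of the other shifts was not tested.

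The replicate number as a block gave 3 higher probe sets, against 8. Of these, only Retnla and Chil4 were among the 8. The third was Dcpp2, one of the gland genes, with a limma adjusted p of 0.716 without the block. No sign was seen that shared numbers pair the samples. Deviations of same-numbered samples correlated at -0.067, -0.12 and -0.13, and 0 of 6 samples correlated best with their own number. Transcripts of other tissues on single arrays may hide a shared batch, so pairing is not excluded.

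Retnla and Chil4 kept their calls in all 19 alternatives run for them. Scaling moved the median log2 fold change of all probe sets by at most 0.015. Dim genes rest on signals near the low-signal range, and their folds shrink with a pseudocount of 16.

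Directions turned for some lists and genes, none past the threshold with all arrays. For lists this is the direction of the test, and the median need not turn with it. With both left out, list medians were -0.057 for MHC class II, 0.023 for epithelial junctions, -0.038 for eicosanoid synthesis, 0.060 for ciliated cells, -0.071 for monocytes, 0.0089 for B cells, -0.013 for mast cells and -0.021 for cartilage. Log2 fold changes were -0.21 for Il33, 0.079 for Foxj1 and 0.013 for Scgb1a1. Without shared members, medians were 0.029 for alarmins and 0.0073 for club cells. Mast cells above the median gave 0.013. B cells gave 0.036 with quantile normalization, 0.051 with median centring and 0.067 with the replicate block. Scgb1a1 gave 0.046 with quantile normalization and 0.00879 scaled to the 75th percentile.

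With 1 array left out, medians ranged from -0.121 to 0.082 for alarmins, -0.094 to 0.206 for MHC class II, -0.222 to 0.0013 for airway remodelling, -0.018 to 0.022 for epithelial junctions, -0.048 to 0.060 for eicosanoid synthesis and -0.142 to 0.045 for ciliated cells. They ranged from -0.052 to 0.044 for tuft and neuroendocrine cells, -0.019 to 0.081 for monocytes, 0.043 to 0.076 for B cells, 0.0066 to 0.105 for mast cells, -0.286 to 0.126 for endothelial cells and -0.128 to 0.097 for cartilage. Il33 ranged from -0.14 to 0.25 and Scgb1a1 from -0.036 to 0.040. The cause of these turns was not tested.

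Log2 fold changes of further named genes, none past the threshold, moved by over 1.5 times. With 1 array left out, they ranged from 0.56 to 1.03 for Ccl6, 0.35 to 0.73 for Ccl9, 0.27 to 1.29 for Ccl11, 0.20 to 0.62 for Tslp, 0.0069 to 0.19 for Il25, 0.43 to 0.81 for Zbp1, 0.55 to 1.27 for Mx1, -1.74 to -0.74 for Hspa1a, -0.25 to -0.028 for Foxj1 and 0.13 to 0.56 for Ctss. Acta2 ranged from -1.21 to -0.50 and Cnn1 from -1.41 to -0.51. With both left out, they were 0.41 for Mx1, 0.47 for Mcm3, -0.35 for Fmo2, 0.48 for Ces1f, -0.21 for Tekt2 and 1.01 for Cxcl15.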

Other observations

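Another 5 lists were added after the leading genes were known, from which genes already seen were left out. They covered secretory machinery outside the fixed lists, ion transport, lipid synthesis and ribosomal proteins. The tests on these lists were set before their results were seen. All 26 measured genes of the translocon, signal peptidase and N-glycosylation had log2 fold changes above 0, with a median of 0.34 (camera adjusted p over the 5 lists = 2.9e-20). Among them, Ddost averaged 2023 ± 64.5 against 1458 ± 86.7 and Rpn1 1841 ± 93.1 against 1362 ± 52.8 (SD, n = 3 per group). Adjusted over the list alone, 20 rose, and 0 passed over all genes. COPI, COPII and Golgi traffic genes, with 28 of 28 above 0, gave 4.3e-13, and the KDEL receptor Kdelr3 differed 1.57-fold. The estimated correlation gave adjusted p = 0.0996 and 0.107 for the translocon and traffic lists, and limma's fry gave 0.0135 and 0.0260. The call depends on the test, so a coordinated rise is a hypothesis, which may be followed in more samples.

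Genes of cholesterol and fatty acid synthesis were higher as a group (camera adjusted p = 5.0e-05, and adjusted p = 0.057 with an estimated correlation), with Fdps at 701 ± 101 against 463 ± 75.2. Cytoplasmic ribosomal protein genes were lower as a group, with 0 of 20 above 0 and a median of -0.18 (8.2e-09, and adjusted p = 0.138 with an estimated correlation). Ion and fluid transport genes, tested because Slc26a4 and Kcnk6 rose, did not pass (0.984). With fry, the adjusted p was 0.012 for cholesterol and fatty acid synthesis, 0.060 for ribosomal proteins and 0.839 for ion transport. All genes of these lists named here were chosen after their values were seen.

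Other splits of the 6 arrays bear on both counts. The real split gave 8 probe sets and the highest other 0, as 1 of 10 splits with a count as large. For lists the real split gave 13 and the highest other 12, again as 1 of 10. With 10 splits, a share under 0.05 cannot be reached. Of the 13 lists, 7 had their lowest p in the real split, among them mucus (unadjusted p = 1.5e-24, lowest other 1.5e-07), the unfolded protein response (5.3e-15 and 7.2e-05) and type 2 (3.3e-13 and 0.0028). The other 6 had a lower p in another split, among them interferon (5.5e-05 and 5.9e-24), cell cycle (1.8e-10 and 1.1e-21) and fibroblast genes (0.0056 and 1.2e-14).

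Of the tests below, 4 were chosen after the result was seen, both of gland genes against the challenge and both on Retnlg. Skeletal muscle transcripts on Alternaria replicate 2 were tested on 20 muscle genes not looked at before. Their median lay 4.93 above the median of the other 5 arrays on the log2 scale, and 18 were over 2-fold higher, so muscle tissue carried in with the sample is a candidate explanation. Tnnt3 reached 22861 and Ckm 4375. The challenge as the cause is argued against by Alternaria replicates 1 and 3, where the same genes were not raised. Their median over the other 5 arrays was -0.42 and -0.24 there, against -0.28 and 0.17 on PBS replicates 1 and 2. Against the mean of all PBS arrays, their median on Alternaria replicates 1 and 3 was -1.05. PBS replicate 3 also carried these genes, with a median of 2.02 over the other 5 arrays, which pulls that value down. Chga, which the parathyroid also makes, read 3122 on Alternaria replicate 2 and 82.0 to 99.8 elsewhere.

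Exocrine gland transcripts stood out on PBS replicate 1, where Prol1 read 34502 and Pip 4046. Gland tissue or its secretion in the sample could bring them, but gland genes not looked at before lay higher there than on PBS replicates 2 and 3 by a median of only 0.53, between the bounds set, which keeps this open. The 8 gland genes first listed lay above PBS replicates 2 and 3 on PBS replicate 1 by a median of 9.09 and at least 1.67 on the log2 scale. They were listed because they stood out, so this height was largely fixed in advance. It is the design that argues against the challenge on that array, since PBS replicate 1 was not given Alternaria. On all 3 Alternaria arrays, 6 of the 8 were above PBS replicates 2 and 3. On Alternaria replicate 1, however, these 6 read only 7.39 to 81.7, near or in the low-signal range. Car6 read 67.3 there, against 59.6 and 59.1 on PBS replicates 2 and 3, and Mucl2 70.6 against 12.7 and 4.48. The count thus cannot decide the question, and the genes were picked for standing out. For Alternaria replicates 2 and 3 a response to the challenge stays open.

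Retnlg is known as a neutrophil transcript. Neutrophils in the brushings are argued against by the other 21 neutrophil markers without Lcn2, whose median log2 fold change was 0.10 and highest 0.51. The abundant neutrophil transcripts S100a8 and S100a9 read 96.7 ± 12.7 against 100.5 ± 11.9 and 39.3 ± 1.17 against 36.6 ± 1.71. Most of the 21 averaged under 73.9 in both groups, in the low-signal range, which limits this argument. Ltf, the brightest at 9001 ± 479 after Alternaria, was also counted among the gland genes. Signal of the paralog Retnla on the Retnlg probe set may account for the rise. Over the 3 Alternaria arrays the Retnlg rise was 2.69%, 4.15% and 3.06% of Retnla, a largest over smallest ratio of 1.55. That is above the 1.5 set as a bound against this explanation, but a simulated spread at a constant share gave a 95th percentile of 1.89. The simulation used the residual SD of both genes on these same arrays. That SD already holds the differences tested, so it is not array noise alone and cannot decide the question. It was added after the ratio was seen, and without it the ratio would count against the paralog. The explanation stays open.

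The thyroid genes Pax8 and Iyd were lowest on Alternaria replicate 2, where Pax8 read 32.7 and Iyd 81.5, against 103 to 306 and 217 to 717 on the other 5 arrays. Among probe sets with no gene symbol here, 10340244 and 10341124 were lower after Alternaria when all 35557 were tested, with log2 fold changes of -5.57 and -5.40 and adjusted p of 0.016 and 0.025 in limma. They read at most 0.690 on each Alternaria array and averaged 58.2 ± 19.0 and 45.3 ± 21.4 on PBS arrays, within the low-signal range. On each of the arrays, 0.849% to 1.38% of all probe sets read under 1, so such low readings were not particular to them.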
